A study of Camellia sinensis with 6 samples.

How the data were processed

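Total RNA was taken from young shoots with a plant RNA column kit and made into libraries with a standard Illumina RNA kit, per the labels' protocols, which name no step that selects or removes classes of RNA. The 6 libraries form 2 groups of 3, high and low temperature, as the sample titles give them. The authors deposited a table of raw counts per gene model and a table of FPKM for the same gene models. Per the submitters' processing notes the tools were CASAVA 1.8.2, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and R 4.1.0, with no roles or settings given. The genome build and the strand setting of the counting are not given in the sources used here, so reads of a gene and an antisense partner cannot be told apart. Names, descriptions and coordinates were used as the deposited tables give them, and "sequence 3" means the assembly sequence with that number. The reference gene table at hand shares no identifiers with the tables and was not used. Bisulfite sequencing, named in the series title, was not analysed here.

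The deposited FPKM values equal count divided by gene length and by 1 divisor per library, which follows the median-of-ratios size factor and not the library total. For high-temperature replicate 2 the divisor was 1.13 times the library total, against 0.977 to 1.01 times in the other libraries. Gene models from the gene caller all have lengths that are multiples of 3, so length is coding length. The counts hold 6562 loci outside the annotated gene models, and 9778 gene models have no description. A count of 3, the level treated as the floor, is 0.197 CPM in the shallowest library, and such floors cover counting error only.

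Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM scaling, filterByExpr with a minimum count of 10, group as the only term) and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Standard errors were taken from the log2 change and its F value. The 19 gene lists were fixed as word patterns before the data were examined and matched on the whole description, which also let in genes whose domain text holds the words. Lists with at least 5 and domain families with at least 10 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and repeated with an estimated correlation and, for lists, with fry, which tests whether a list moves on balance 1 way. P-values were adjusted over the lists or the families. Named genes followed a rule fixed beforehand: the 2 members with the smallest p of each main list and 1 of each other list, plus the 3 largest rises and 3 largest falls with non-overlapping groups, at least 10 CPM in the higher group and a named product. CPM are scaled by TMM.

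Alternatives were other scalings, other count filters, the replicate number as a block, each library left out, DESeq2 1.42.0, limma on log2 FPKM (a pseudocount of 1 or 0.1 with a filter at a mean FPKM of 0.5, and a pseudocount of 1 without that filter), a test against a 2-fold change and an adjusted p under 0.01. Chosen after seeing the data were matching lists on the protein name alone, leaving out plastid-encoded proteins and scaling by library totals only. The steps were tested on simulated counts for the 26767 tested gene models with the libraries' own means, sizes and dispersions. For low against high temperature, 26% of 50 genes changed 1.5-fold were recovered, 70% at 2-fold, 98% at 4-fold and 98% at 8-fold. Of 26527 unchanged genes 8 were called, and none of 30 unchanged lists was called by camera (adjusted p of the changed list 1.79e-29). Genes were simulated independently of each other and the unchanged lists held random genes. The simulation therefore cannot show how often camera calls unchanged lists whose genes move together. Replicate pairs differed by a mean chi-square of 5.40 to 26.5 per gene, where sampling noise alone gives about 1, so none were merged.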

Results

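RNA levels were measured by RNA sequencing in young shoots of the tea plant cultivar 'Zhonghuang 2', whose new leaves yellow in the cold. Plants first spent 1 month at 22 °C, then stood in 1 of 2 climate chambers with 12 h of light and 12 h of dark. The high-temperature chamber, the control, ran at 26 °C by day and 22 °C by night, and the low-temperature chamber at 18 °C and 14 °C. Green shoots from the first and yellowed shoots from the second were taken once the cold-grown leaves had turned yellow, and each group has 3 libraries. Counts summed to between 15202546 and 15642015 per library over 40118 gene models. Each temperature had a chamber of its own, so temperature and chamber cannot be told apart. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical.

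The comparison asks which genes differ between yellowed shoots grown in the cold and green shoots grown in the warm. At low temperature 13 of 30 genes for chlorophyll-binding antenna proteins fell, as did a protochlorophyllide reductase, while 38 of 149 genes for plastid gene expression and protein import, chlorophyll synthase and Rubisco activase rose. A glutathione S-transferase of class F12 fell 67.8-fold. A heat shock cognate 70 kDa protein fell 6.55-fold, while in the HSP70 domain family 4 of 27 members rose and 4 fell. Of 26767 gene models tested, 5062 were called at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2480 higher and 2582 lower at low temperature. At least 2-fold changes were fewer, 470 higher and 812 lower. Without low-temperature replicate 2 the number called was 2606, and without low-temperature replicate 3 it was 2681. Libraries of the 2 groups did not overlap in 36.5% of the tested gene models, where chance gives 10%. The first principal component held 46.4% of the variance and separated the groups, and the second, with 17.1%, set high-temperature replicate 2 apart. That library differed from the other high-temperature libraries by a mean chi-square of 26.5 and 23.0 per gene, against 5.40 between those 2 libraries. Without it 5621 gene models were called.

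**Figure D1:**
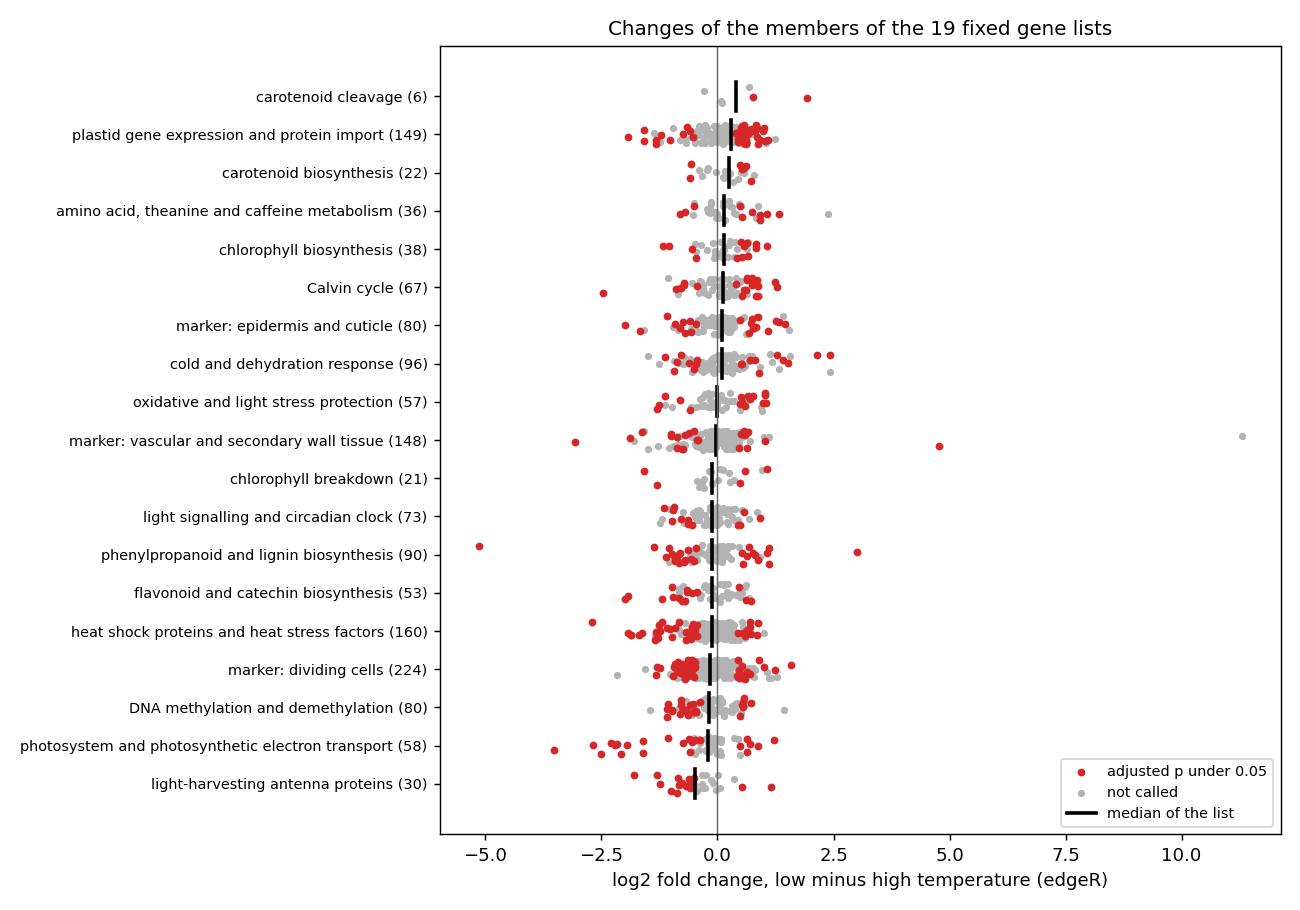
Log2 fold change, low minus high temperature, of every tested member of the 19 gene lists fixed before the data were examined, with the number tested in parentheses. Red points passed an adjusted p under 0.05, grey points did not, and the black line is the list's median, lowest for the antenna list at -0.48. One grey point of the vascular list lies far to the right and was not called.

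Light-harvesting antenna proteins, which bind chlorophyll and feed the photosystems, made up the list with the lowest median, -0.48 on the log2 scale. Of 30 tested members 13 fell, 2 rose and 15 did not pass the test, and adjusted over the list alone 18 fell and 3 rose. The list was called lower (camera, adjusted p = 0.00051), but with an estimated correlation the adjusted p = 0.617, and fry's directional test gave an adjusted p of 0.0818. Chlorophyll a-b binding protein 4 (Cha03g010840, sequence 3, 118540963 to 118542694, minus strand) fell from 885 ± 114 to 372 ± 4.75 CPM (SD, n = 3), a log2 change of -1.25 ± 0.16 (SE) with an adjusted p of 4.5e-05. Chlorophyll a-b binding protein 40 (ChaUn21920.1) fell from 1386 ± 312 to 562 ± 8.37 CPM. There are 6 gene models with that protein name, and reads may be split among them. The summed level of the list was 48610 CPM in high-temperature replicate 1 and 48423 CPM in replicate 3, but 32796 CPM in replicate 2, nearer to the 28310 to 29381 CPM of the low-temperature libraries.

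Photosystem and electron transport proteins were called lower as a list of 58 tested members (camera, adjusted p = 0.00778), with 18 that fell, 6 that rose and a median of -0.20. With an estimated correlation the adjusted p = 0.486. Adjusted over the list alone, 23 fell and 9 rose. Leaving out 1 library gave medians from -0.32 to -0.15. Without gene models of proteins that plants encode in the plastid genome, 50 members were tested, their median was -0.13 and the list was not called (adjusted p = 0.139), an alternative chosen after seeing the data. PsbR, the 10 kDa polypeptide of photosystem II (Cha08g018420, sequence 8, 150071039 to 150072433, plus strand), fell from 227 ± 9.57 to 73.9 ± 13.9 CPM, a log2 change of -1.62 ± 0.15 (adjusted p = 1.83e-06). A carboxyl-terminal-processing peptidase (Cha13g000590), a protease of the class that trims a photosystem II subunit, fell from 55.1 ± 5.15 to 14.2 ± 1.70 CPM.

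Chlorophyll biosynthesis enzymes moved in both directions. Of 38 tested members 9 rose and 4 fell, or 10 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.139). A protochlorophyllide reductase (ChaUn14930.2), the light-requiring step before chlorophyllide, fell from 162 ± 19.4 to 79.1 ± 12.1 CPM, a 2.05-fold difference (log2 change -1.04 ± 0.15, adjusted p = 0.000123). It is 1 of 4 gene models with that protein name, so the step as a whole need not have fallen. Chlorophyll synthase (Cha10g004040, sequence 10, 24571082 to 24578180, minus strand), which attaches the phytol tail in the last step, rose from 64.6 ± 3.24 to 115 ± 9.42 CPM (log2 change 0.83 ± 0.13, adjusted p = 0.000263). In chlorophyll breakdown 3 of 21 tested members rose and 2 fell, with 3 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.956). Both leading members were chlorophyllases, which remove the phytol tail. A chlorophyllase-2 (ChaUn7748.1), 1 of 6 gene models with that protein name, fell from 28.1 ± 2.53 to 11.4 ± 0.658 CPM. Chlorophyllase-1 (Cha05g004350) rose from 10.1 ± 0.104 to 21.2 ± 3.59 CPM.

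Plastid gene expression and protein import was the only list of the 19, matched on the whole description, called higher (camera, adjusted p = 0.00145, but adjusted p = 0.486 with an estimated correlation). Of 149 tested members 38 rose and 11 fell, with a median of 0.28, and adjusted over the list alone 50 rose and 13 fell. TIC 20-I (Cha12g003820, sequence 12, 21070192 to 21072378, plus strand), a subunit of the import channel in the inner envelope, rose from 103 ± 11.8 to 202 ± 4.63 CPM, a log2 change of 0.98 ± 0.13 (adjusted p = 0.000103). TIC 32 (Cha01g008730), named as a short-chain dehydrogenase of the import machinery, went the other way, from 51.6 ± 7.10 to 13.5 ± 2.90 CPM, and 12 gene models carry its protein name. In the Calvin cycle list 15 of 67 tested members rose and 6 fell, or 16 and 7 adjusted over the list alone. That list was not called (adjusted p = 0.095), and 28 of its 67 tested members were matched by domain or other text and not by protein name. Matched by protein name alone, a choice made after seeing the data, the list was called higher (adjusted p = 0.0185), with 10 of 39 tested members that rose, 2 that fell and a median of 0.24 against 0.12. Fry also called it, and over its 16 alternatives the adjusted p ran from 0.0185 to 0.607, the highest with an estimated correlation. Rubisco activase 1 (Cha11g006560), which restores Rubisco's active site, rose from 389 ± 3.31 to 914 ± 156 CPM, a 2.35-fold difference. A plastid fructose-1,6-bisphosphatase (ChaUn8386.2) rose from 58.8 ± 3.20 to 108 ± 4.71 CPM. The most abundant Rubisco small chain model (Cha06g019690) went the other way. It held 0.593%, 0.728% and 0.631% of the counts in high-temperature replicates 1, 2 and 3. Its share was 0.408% and 0.385% in low-temperature replicates 2 and 3. In low-temperature replicate 1 it was not among the 10 highest genes, the last of which held 0.372%.

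**Figure D2:**
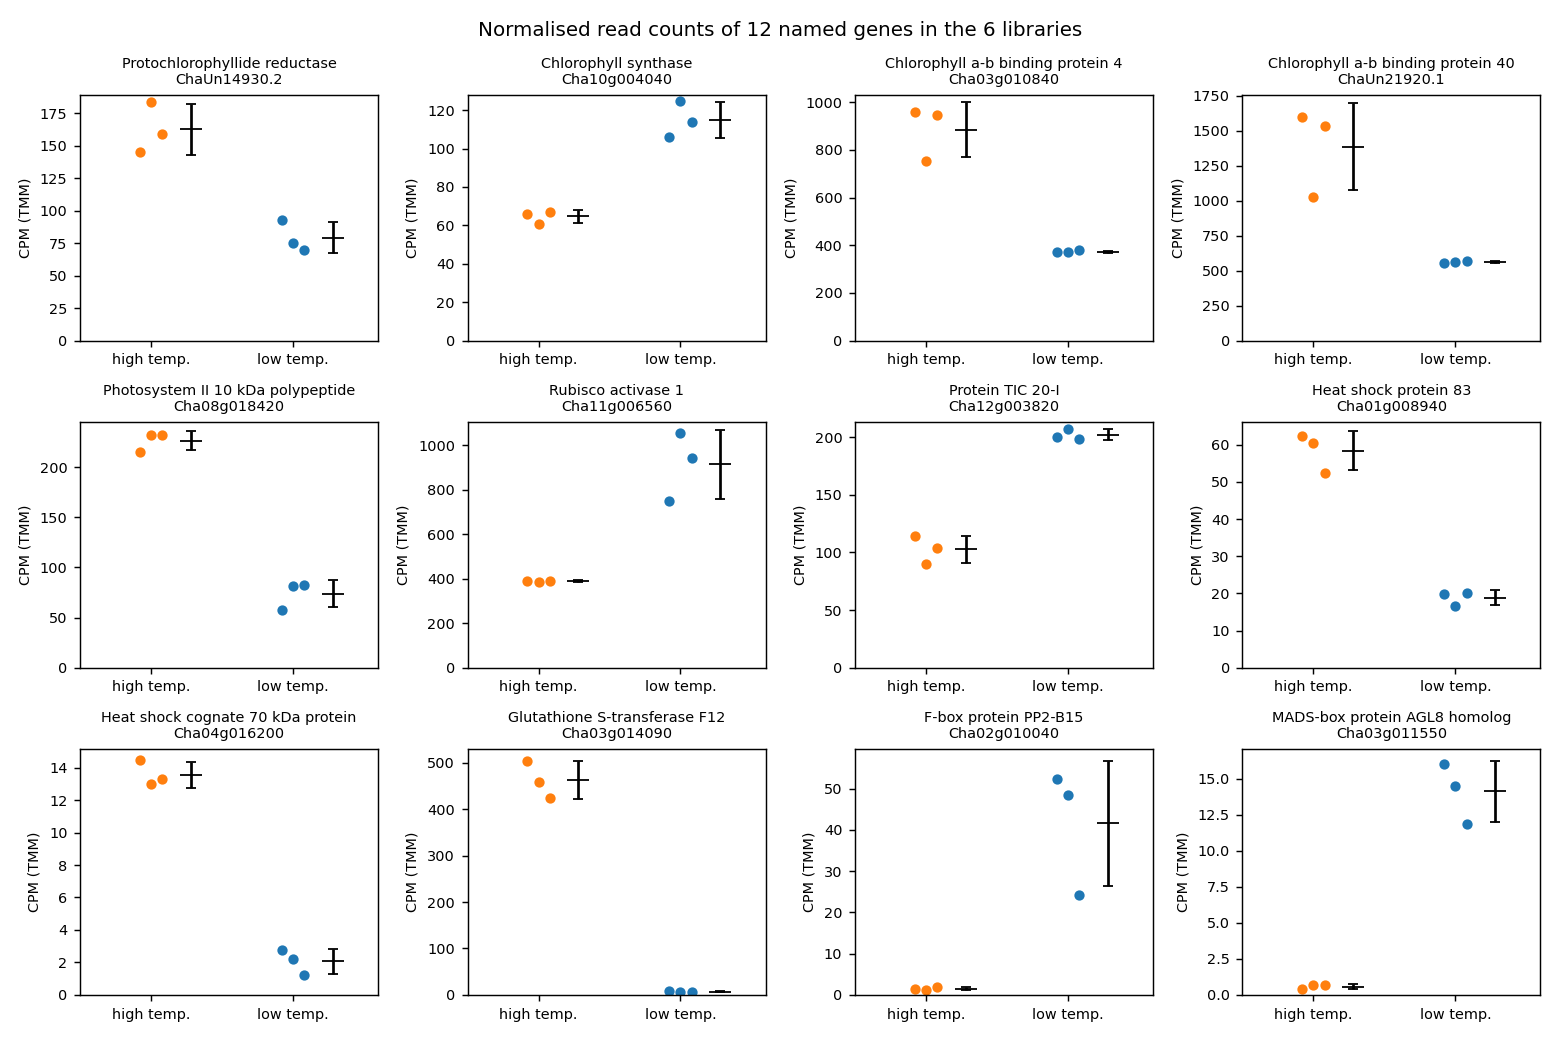
Normalised read counts (CPM with TMM scaling, axes from 0) of 12 named genes in each of the 6 libraries, orange for high and blue for low temperature. Black marks give the mean and SD of the 3 libraries of a group. The 2 groups do not overlap in any of the 12 genes, from glutathione S-transferase F12 at 463 and 6.82 CPM to TIC 20-I at 103 and 202 CPM. The genes were picked for small p-values or large changes, so this separation follows from the choice.

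Carotenoid biosynthesis, flavonoid and catechin biosynthesis and phenylpropanoid biosynthesis were not called as lists by camera, each at an adjusted p of 0.139. Without high-temperature replicate 2 the flavonoid list was called lower (adjusted p = 0.0275, from 0.0275 to 0.745 over its alternatives), with a median of -0.21 against -0.12, but leaving out any other library did not call it and the median ranged up to -0.04. Fry called the carotenoid list (adjusted p = 0.0499) and the phenylpropanoid list (0.0341), whose adjusted p reached 0.533 and 0.486 with an estimated correlation. Carotenoid enzymes had 5 of 22 tested members that rose and 2 that fell, or 6 and 3 adjusted over the list alone. Phytoene synthase (Cha01g015520), the entry step, fell from 98.3 ± 12.4 to 65.2 ± 2.09 CPM, and beta-carotene hydroxylase 2 (Cha01g008920) rose from 73.9 ± 17.9 to 122 ± 11.3 CPM, a call lost with unfiltered FPKM (adjusted p = 0.0502, the highest of its 16 alternatives, the lowest being 0.000361). Among carotenoid cleavage enzymes 2 of 6 rose and none fell (adjusted p = 0.139). NCED3 (Cha07g008460), the 9-cis-epoxycarotenoid dioxygenase on the path to abscisic acid, rose from 3.62 ± 1.23 to 13.7 ± 0.239 CPM. Of 53 tested flavonoid and catechin members 13 fell and 3 rose, with the same numbers adjusted over the list alone. Leucoanthocyanidin reductase (Cha10g012330), which makes catechin, fell from 40.6 ± 6.51 to 17.7 ± 5.33 CPM. The other member named by the rule (ChaUn9118.2, 950 ± 76.6 to 480 ± 105 CPM) carries the protein name fatty-acid-binding protein 1 and was matched by other text. Among phenylpropanoid and lignin genes 17 of 90 fell and 11 rose, or 21 and 11 adjusted over the list alone. A probable cinnamyl alcohol dehydrogenase (ChaUn8766.1) fell from 41.6 ± 1.85 to 22.1 ± 1.56 CPM.

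Heat shock proteins and heat stress factors had 32 of 160 tested members that fell and 10 that rose, or 35 and 10 adjusted over the list alone. The list was not called (camera, adjusted p = 0.095) but was by fry (0.0499) and by protein name (0.0473), with an adjusted p of up to 0.607 with an estimated correlation. Of its 160 tested members 76 were matched by text other than the protein name, among them histidine kinases. Heat shock protein 83 (Cha01g008940), of the HSP90 class of chaperones, fell from 58.4 ± 5.35 to 18.9 ± 1.91 CPM (log2 change -1.63 ± 0.14, adjusted p = 1.08e-06). A heat shock cognate 70 kDa protein (Cha04g016200) fell from 13.6 ± 0.799 to 2.07 ± 0.766 CPM (log2 change -2.71 ± 0.27). There are 6 gene models with that protein name, and in the HSP70 domain family 4 of 27 members rose and 4 fell, with a median of -0.064. For cold and dehydration response 10 of 96 rose and 8 fell (11 and 8 adjusted over the list alone), and the list was not called (adjusted p = 0.289). Of those 96, 58 were matched by text other than the protein name. The list's 2 leading members, ChaUn6663.1 and ChaUn6663.2, fell 1.91-fold and 1.83-fold. They are neighbouring gene models named as galactinol synthases, enzymes of raffinose synthesis. Their coding lengths are only 303 and 312 bases, and both lie on the minus strand of the same sequence. Whether they are parts of a single gene was not tested, so they may not be separate observations. DNA methylation and demethylation had 21 of 80 members that fell and 6 that rose, or 23 and 8 adjusted over the list alone, and was not called (adjusted p = 0.0724). It was called lower in 4 of 16 alternatives, with the stricter count filter (adjusted p = 0.0439), without high-temperature replicate 1 (0.0413), without low-temperature replicate 1 (0.0247) and by protein name (0.049), and the adjusted p reached 0.617 with an estimated correlation. DEMETER (Cha08g007390), a DNA glycosylase that removes 5-methylcytosine, fell from 67.8 ± 9.07 to 34.4 ± 5.43 CPM, and 4 gene models carry its protein name. Methyl-CpG-binding protein 11 (Cha06g012040) fell from 151 ± 10.8 to 76.2 ± 14.3 CPM.

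Markers of other cell types and states gave no called list with all 6 libraries. Dividing-cell genes had 44 of 224 members that fell and 14 that rose (49 and 15 adjusted over the list alone, camera adjusted p = 0.0908), led by cyclin-A2-1 (Cha12g007010), which fell from 50.2 ± 5.88 to 19.9 ± 4.94 CPM. That list was called lower without high-temperature replicate 2 (adjusted p = 0.0323) and without low-temperature replicate 1 (0.0247), and over its 16 alternatives the adjusted p reached 0.607. Vascular and secondary wall genes had 9 of 148 that rose and 14 that fell (6 and 8 adjusted over the list alone, adjusted p = 0.922), and their median and mean differed in sign. Of the 148, 107 were matched by domain or other text and not by protein name, so many may not mark that tissue. Matched by protein name alone, a choice made after seeing the data, 41 were tested, 1 rose and 3 fell. That list was not called either (camera, adjusted p = 0.269). The leading member of the 148, PP2-B15 (Cha02g010040), an F-box protein matched by its domain text, rose from 1.52 ± 0.446 to 41.6 ± 15.2 CPM. Epidermis and cuticle genes had 11 of 80 that rose and 10 that fell (15 and 11 adjusted over the list alone, adjusted p = 0.552). The wax ester acyltransferase WSD1 (Cha03g004530) fell from 429 ± 43.1 to 134 ± 4.53 CPM. Stress protection genes had 11 of 57 that rose and 5 that fell (11 and 7 adjusted over the list alone, adjusted p = 0.683). A cytosolic ascorbate peroxidase (ChaUn26193.2), 1 of 5 gene models with that protein name, fell 2.38-fold. Light signalling and clock genes had 4 of 73 that rose and 8 that fell (2 and 8 adjusted over the list alone, adjusted p = 0.20). Of those 73, 29 were matched by text other than the protein name. In that list bHLH63 (Cha02g017350), a partner of cryptochrome, fell 1.93-fold. In amino acid, theanine and caffeine metabolism 7 of 36 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.13), and fry called the list (adjusted p = 0.0369, up to 0.533 over its alternatives). Arginine decarboxylase 2 (ChaUn9916.2), a polyamine enzyme, rose from 102 ± 25.2 to 254 ± 26.7 CPM.

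The largest rises among genes past the test and with at least 10 CPM were an F-box protein with a phloem protein 2 domain, PP2-B15 (Cha02g010040), a MADS-box factor named as a homolog of AGL8 (Cha03g011550) and a prolyl endopeptidase (Cha09g000820). PP2-B15 rose from 1.52 ± 0.446 to 41.6 ± 15.2 CPM, a log2 change of 4.78 ± 0.32 (adjusted p = 1.3e-06). The AGL8 homolog (sequence 3, 121830552 to 121869410, plus strand) rose from 0.575 ± 0.145 to 14.1 ± 2.13 CPM, a log2 change of 4.59 ± 0.29 (adjusted p = 1.97e-08). The endopeptidase had 25.2 ± 15.7 CPM at low temperature against 0.862 ± 0.557 (adjusted p = 0.0177), and lost its call without any 1 of the high-temperature libraries (adjusted p of 0.0935, 0.0889 and 0.0779 without replicates 1, 2 and 3). Glutathione S-transferase F12 (Cha03g014090, sequence 3, 136532741 to 136639790, plus strand), of the class that carries anthocyanins to the vacuole, fell from 463 ± 40.2 to 6.82 ± 0.58 CPM, a log2 change of -6.08 ± 0.18 (adjusted p = 1.84e-13). High affinity nitrate transporter 2.4 (Cha11g004520) had 529, 312 and 315 counts in the high-temperature libraries and 3, 0 and 3 in the low-temperature ones (adjusted p = 6.35e-08). An enzyme named S-norcoclaurine synthase 1 (Cha14g005370) had 179, 172 and 139 counts against 1, 7 and 3 (adjusted p = 1.46e-07). These low counts are too few for a fold to be given.

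Protein domain families of the deposited annotation were tested in the same way, and 20 of 224 were called, 15 higher and 5 lower. With an estimated correlation no family was called by camera, and the smallest adjusted p = 0.767, while 56 had an unadjusted p under 0.05 with the preset one. ESCRT-III proteins, which sever membrane necks, had 13 of 19 members that fell and a median of -0.61 (adjusted p = 2.81e-05). Kinesin motors had 27 of 80 that fell and none that rose (adjusted p = 0.000282). Among families called higher, KH-domain RNA-binding proteins had 12 of 36 members that rose, mitochondrial carriers 24 of 80 and GRAS transcription factors 14 of 51. The share of counts in the 10 highest genes was 5.15% ± 0.549 at high and 4.63% ± 0.114 at low temperature (SD, n = 3; exact two-sided permutation p = 0.4, where 0.1 is the smallest possible).

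**Figure D3:**
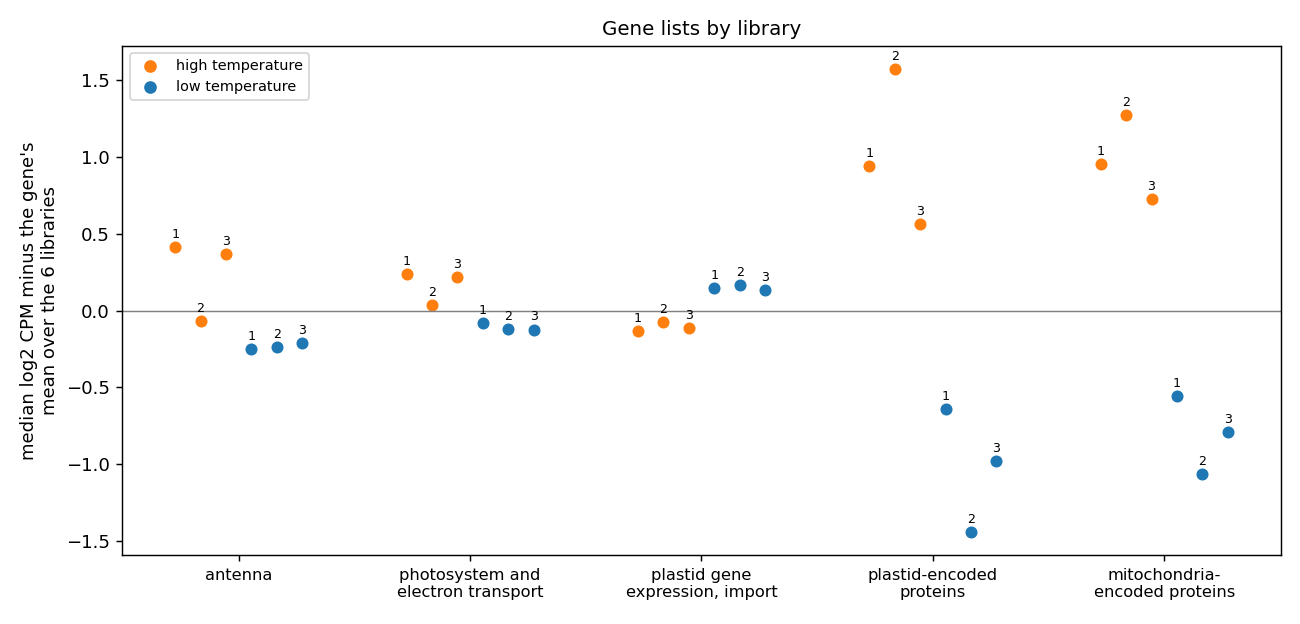
Median over a list's genes of log2 CPM minus the gene's mean over the 6 libraries, for 5 lists, with replicate numbers above the points, orange for high and blue for low temperature. High-temperature replicate 2 has the lowest antenna value of its group, -0.07, and the highest for plastid-encoded proteins, 1.57. The 2 lists of organelle-encoded proteins were chosen after their values were seen.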

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

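Tests chosen only after the data were seen were the 3 alternatives of protein-name matching, plastid-encoded proteins left out and library totals. The number of genes called lay within 1.5 times of 5062 under the scalings, count filters, DESeq2 and both filtered FPKM tests. It was 2980 with unfiltered FPKM (1474 higher, 1506 lower; 291 and 493 at least 2-fold), 2423 at an adjusted p under 0.01 (1178 and 1245), and 158 in the test against a 2-fold change (41 and 117). Fewer genes pass the last 2 by construction; for FPKM the cause was not tested. Leaving out 1 library gave 2606 to 5621 genes, 1267 to 2892 higher and 1337 to 2729 lower, with the low values without low-temperature replicates 2 and 3 (2606 and 2681). Of the 2606, 2558 were among the 5062 with the same direction. At least 2-fold changes ranged from 343 to 567 higher and from 623 to 882 lower. Called lists numbered 3 and ranged from 3 to 5 without 1 library (5 without high-temperature replicate 2, which added the flavonoid and dividing-cell lists, or low-temperature replicate 1, which added the DNA methylation and dividing-cell lists). They numbered 0 with camera's estimated correlation (7 at an unadjusted p under 0.05 with the preset one), 7 by fry, of which 2 were among the 3, and 6 by protein name. Fry asks another question, and the other causes were not tested. Of the 3 lists added by protein name, the Calvin cycle was called higher (adjusted p = 0.0185), while heat shock (adjusted p = 0.0473) and DNA methylation (0.049) lie at the threshold and shifted when the reading of names was corrected. Called families numbered 20, from 16 to 24 without 1 library and 0 with an estimated correlation. The replicate numbers do not pair the libraries (correlations of deviations -0.0113, 0.0399 and -0.00939), and the replicate block gave 4805 genes, 3 lists and 22 families. Direction turned, never past the threshold, for chlorophyll breakdown (medians -0.12 without a filter, -0.10 with the block, -0.17 to 0.0055 without 1 library, -0.11 by fry, -0.13 by protein name), the vascular list (-0.021 without a filter, -0.041 to 0.027 without 1 library) and the cold list (-0.057 by protein name); there the median and the test can differ in sign, and the cause was not tested. The top-10 share difference ranged from -0.828 to -0.328 percentage points without 1 library. Named genes kept their side of the threshold and direction in 556 of 560 combinations of gene and setting and lost the call in 4, 3 of them the endopeptidase and 1 beta-carotene hydroxylase 2. These genes were picked for small p-values or large changes in the main fit, so most such agreement is built in. The test against a 2-fold change and the adjusted p under 0.01 were left out of these combinations. The endopeptidase (edgeR, adjusted p = 0.0177) does not pass the latter. In the simulation 2-fold changes were recovered in 70% of changed genes and 1.5-fold changes in 26%, so smaller differences may have been missed. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter, and genes with low counts were not changed. These shares are therefore not the sensitivity of the real comparison.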

Other observations

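Of the tests in this part, the comparison of mitochondria-encoded with plastid-encoded gene models, the dividing-cell test and the correlations of high-temperature replicate 2 were chosen only after the result was seen. The gene groups in the next paragraph were also chosen after their values were seen, as were their names.

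Of 15 genes tied to anthocyanin pigments, glutathione S-transferase F12 and 3 others fell, 1 rose and 10 did not pass the test, with a median of 0.05. The factor MYB75 (Cha01g017900), an activator of anthocyanin synthesis in other plants, fell from 35.7 ± 2.37 to 2.94 ± 1.16 CPM (SD, n = 3), and an anthocyanin malonyltransferase (Cha13g012390) fell from 22.7 ± 2.47 to 3.98 ± 0.484 CPM. Among zinc transporters and nicotianamine synthases, which make a metal chelator, 6 of 13 rose and 2 fell. Measures of the whole group differed: the median log2 change was -0.14, while the summed level went from 229 to 514 CPM. The members that fell were zinc transporter 11 (Cha05g015380) and a zinc transporter 1 (Cha04g015300). Zinc transporter 4 (Cha12g005720) rose from 19.9 ± 4.76 to 164 ± 17 CPM and a nicotianamine synthase (Cha02g010480) from 4.32 ± 1.04 to 42.6 ± 15.6 CPM. Nitrate reductase (Cha04g009830) fell from 134 ± 16.6 to 24.1 ± 2.09 CPM and nitrite reductase (Cha02g016130) from 69.2 ± 14.5 to 16.4 ± 5.49 CPM, while 5 of the 63 nitrate genes rose and 6 fell. In sulfate assimilation 6 of 28 rose and 5 fell, among the risers 5'-adenylylsulfate reductase 1 (Cha07g014260) from 56.6 ± 12.4 to 138 ± 29.5 CPM.

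Gene models of proteins that plants encode in the plastid fell, 16 of 21 with none that rose and a median of -2.17, from a summed 318 to 89.1 CPM. An organelle RNA carry-over that differed between libraries would lower mitochondria-encoded models too. The mitochondria-encoded median was -2.25 over 11 models, a difference of -0.083 from the plastid-encoded ones (one-sided permutation p = 0.616), so this explanation stays open. That comparison is weak, since the 11 models summed to only 41.6 CPM at high and 12.2 CPM at low temperature. Some low-temperature means lay below the floor of 0.197 CPM, such as cytochrome c oxidase subunit 3 (ChaUn2147.118) at 0.0654 CPM. The permutation also treats gene models as independent. One library does not set the fall, since the median was still -1.61 in the fit that left out high-temperature replicate 2, the highest of the 6. A lower organelle transcript level at low temperature also stays open, untested.

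The antenna list was called lower and the plastid gene expression list higher at low temperature with camera's preset correlation, but both calls are lost with an estimated one (adjusted p = 0.617 and 0.486), and fry did not call the antenna list (adjusted p = 0.0818). Among 10000 lists matched on mean expression, 0% had a median as low as the antenna list, with a lowest of -0.33. This argues against compression of abundant genes in general, although such draws treat genes as independent. Matching was within bins of expression rank, so the most abundant antenna genes were set mostly against less abundant genes. Compression limited to the most abundant genes is therefore not settled. A larger share of dividing cells is not settled: the dividing-cell median was -0.17 and the list was not called (camera, adjusted p = 0.0908), yet it was called lower, against this explanation, without high-temperature replicate 2 (0.0323) or low-temperature replicate 1 (0.0247), and 62.5% of its members lay below 0. Of division-related domain families, kinesins were called lower (0 rose and 27 fell of 80, camera, adjusted p = 0.000282, but 0.813 with an estimated correlation). Tubulins (7 rose and 2 fell of 25), cyclins with a C-terminal domain (7 and 3 of 30) and histones (1 and 2 of 37) were not called. The list's summed level was 49520 CPM at high and 53643 CPM at low temperature. That order rests on high-temperature replicate 2 with 38753 CPM, against 55918 and 53889 CPM in replicates 1 and 3 and 48454 to 58399 CPM at low temperature. A looser first rule on the share below 0 would have excluded the explanation, and the stricter rule, which needs the list called with all 6 libraries, was chosen after the share was known; the low-temperature response itself, and the chamber, also stay open.

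High-temperature replicate 2 stood apart from its group. Its mean correlation with the other high-temperature libraries exceeded that with the low-temperature libraries by 0.0232 (0.962 against 0.939), which argues against a low-temperature library under a wrong label. Without the 100 most abundant genes its TMM factor was 1.07 against 1.10, so those genes do not set all of it. A difference between the plants or the RNA of that library stays open, and no biological explanation was tested.

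The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Every split but the real one mixes libraries of both groups, so the difference between the groups adds to the spread within them. Low gene counts in those splits are therefore largely built in. The real split gave 5062 genes and the highest other 1, as 1 of the 10 splits; for at least 2-fold changes the values were 1282 and 1, again 1 split. For lists the real split gave 3 and the highest other 5. Of the 10 splits 5, the real split included, gave 3 or more lists, so the number of called lists does not set the real grouping apart. For families the real split gave 20 and the highest other 17, and only 1 split, the real split, gave as many as 20.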
